A study of Arabidopsis thaliana with 6 samples.

How the data were processed

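The series measured the places on the genome to which Myc-tagged PIF1 was cross-linked in whole, dark-grown Arabidopsis thaliana seedlings, with wild-type seedlings taken through the same immunoprecipitation as background. Seeds received white light for 3 h and seedlings then stayed in darkness for 3 d at 21 °C, per the labels' protocols. Each library pooled 4 immunoprecipitations from 2 biological replicates, and 6 barcoded libraries shared a lane of 50-cycle single-end sequencing, per the labels' protocols. Samples were grouped by the titles and genotype labels, as 3 PIF1 and 3 wild-type libraries.

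The submitters' processing notes name CASAVA 1.8.0, Bowtie 0.12.7, MACS 1.4.1 and the genome build TAIR10. Peaks were called separately for each PIF1 library against 1 wild-type library and not on pooled samples, per the file headers, with an effective genome size of 150000000 bp, a p cutoff of 1e-05, a band width of 300 bp, a model fold range of 10 to 30, a local background over 1000 and 10000 bp and tags of 47 bp. The headers also state a fragment size of 120 bp, at most 3 or 4 tags kept per position, and scaling of the smaller data set towards the larger. Redundant tags made up 13%, 70% and 66% of PIF1 libraries 1, 2 and 3 and 24%, 61% and 15% of the wild-type libraries, per the file headers, so libraries 2 and 3 hold fewer distinct fragments than their totals of 19185319 and 17050217 tags.

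The deposited lists give a tag count per peak, which is the unscaled number of tags of the PIF1 library. They give a score, which the authors' peak caller made as 10 times the negative log10 of its p, with a ceiling of 3100. They give a fold enrichment, a ratio of tags at the peak to the local wild-type background after the scaling named above, per the file headers. They give an FDR in percent, made by the authors' peak caller from the peaks found with PIF1 and wild type swapped. No counts per library outside of peaks were used here, so PIF1 and wild type were not compared by any test beyond the authors' own.

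Peaks of different lists that overlapped by at least 1 bp were merged, and a merged region with peaks of at least 2 of the 3 lists was a consensus region, placed at the mean of its summits. Overlap between lists and location relative to genes were compared with 1000 shuffles over the nuclear chromosomes, with one-sided empirical p. Gene names, gene neighbours and distances came from a gene table of assembly TAIR10.1. Its build name differs from that of the peaks, so none of its coordinates are given. As a check of the match, 35.8% of consensus regions lay inside a gene as placed and 52.1% after moving them by 1000 bp. The table was used without strand, and no genome sequence was used here. The planned window around transcription starts was therefore replaced by 1 that counts a gene where a region lies inside it or within 2000 bp of either end, and classes of exon, intron and untranslated region were not analysed here. The planned motif tests (G-box, PBE-box, all hexamers and fold enrichment by motif) were not analysed here either.

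The 16 gene lists, with 362 members that all matched by locus code, the named-gene rule, the tests and most alternatives were fixed before the data were examined. The lists were written from general knowledge of each pathway and hold selected genes, not whole families. Lists were tested with Fisher's exact test, two-sided, against all other protein-coding nuclear genes, with Benjamini-Hochberg adjustment over the lists. Genes were named by this rule: the 10 regions of all 3 lists with the highest mean percentile of fold enrichment, up to 4 members of each list by the same percentile, every PIF gene, and up to 3 members of each control list. The values of 1 gene that this rule takes are not reported here. Other names are in the closing section and were chosen after their values were seen. Symbols of the gene table stand in brackets where they differ from the listed ones.

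Intervals for shares are 95% Wilson intervals and cover counting error only. Peaks and regions are not replicates, and reads from PCR are not independent molecules. The 3 libraries of a group are independent preparations, but the sources used here do not say whether they share seedlings, so the spread between them may be partly technical. The PIF1 libraries held 5721184 to 14209334 filtered tags, and the deepest, library 1, gave the list with the fewest peaks (4578) and the lowest median fold enrichment (2.71, against 5.29 and 3.87 in lists 2 and 3).

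The scripts were tested on simulated data. Of 200 lists of 25 random genes, 5% had an unadjusted p under 0.05, and of 100 lists of 25 genes drawn with 5 times the odds, 100% did. Simulated peak lists of the real lengths with 0, 500 and 1500 shared sites gave 93, 563 and 1515 regions in all 3 lists and 1805, 2088 and 2658 in at least 2. Alternatives changed the peak threshold, the overlap rule, the number of lists needed, the gene window, the background and the replicates used. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.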

Results

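PIF1 is a basic helix-loop-helix transcription factor that acts in dark-grown Arabidopsis seedlings, where it represses light responses. Chromatin immunoprecipitation with an antibody against the Myc tag was carried out on whole seedlings overexpressing Myc-tagged PIF1 and on wild-type seedlings, which carry no tag and give the background. Seedlings were 3 days old and grown in darkness. There were 3 PIF1 libraries and 3 wild-type libraries, and each peak list compared 1 PIF1 library with the wild-type library of the same number. After removal of excess duplicates the PIF1 libraries held 14209334, 5825479 and 5721184 tags (replicates 1, 2 and 3), and the wild-type libraries 17323572, 6134032 and 7435352. The 3 lists held 4578, 12776 and 7678 peaks, with median lengths of 782, 578 and 534 bp.

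The first comparison asked where PIF1-Myc enrichment over wild type was found repeatedly. Of the 10 strongest regions held by all 3 lists, the first lay beside AT5G02580, the second beside the lysin-motif receptor kinase gene LYK4 and the third beside CKX5, a cytokinin oxidase gene. The regions at ranks 4 and 5 had no protein-coding gene within 2000 bp. PIL1, a light-repressed basic helix-loop-helix gene, and the B-box genes BBX29 and BBX28 lay beside the regions at ranks 7, 9 and 10. The region with the highest mean rank, at chromosome 5, 578446 to 580122 (TAIR10), lay 410 bp outside AT5G02580 and had fold enrichments of 16.25, 49.15 and 40.01 in lists 1, 2 and 3. The region at chromosome 2, 19298638 to 19300041, lay between PIL1 (1208 bp away) and ASY3 (426 bp away), with fold enrichments of 9.99, 66.73 and 38.28. Fold enrichments are the authors' values for single peaks and were used to rank peaks within a list.

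Among the other regions of the top 10, the one at chromosome 2, 10119341 to 10120027, lay 315 bp from LYK4 (12.84, 47.14 and 31.44). That at chromosome 1, 28317680 to 28319430, lay 664 bp from CKX5 (13.71, 45.74 and 29.17). BBX29 had a region 488 bp away at chromosome 5, 22114787 to 22116422, with AT5G54480 1977 bp away, and fold enrichments of 9.31, 44.81 and 30.43. BBX28 had a region 494 bp away at chromosome 4, 13673931 to 13675466 (10.29, 36.63 and 24.71). GH9C3 and MTSSB lay 1517 and 1462 bp from a region at chromosome 4, 6752349 to 6753799 (12.19, 42.11 and 24.54), and AT5G05960 and AT5G05965 lay 1872 and 71 bp from a region at chromosome 5, 1792384 to 1793191 (14.65, 32.1 and 24.1). Of the 10 regions, that at chromosome 4, 9442992 to 9444693, had no protein-coding gene within 2000 bp. Its nearest gene was the homeodomain gene ATHB2 (HB-2 in the gene table), 5181 bp away, and its fold enrichments were 12.58, 46.26 and 27.74. The region at chromosome 1, 10518415 to 10519250, also had none within 2000 bp, with nMAT1 nearest at 2416 bp (11.12, 43.88 and 32.61).

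Merging the lists gave 18378 regions, of which 13533 were found in 1 list, 3455 in 2 lists and 1390 in all 3. The 4845 regions of at least 2 lists are called consensus regions below. Peaks shared with another list made up 46.8% of list 1 (95% Wilson interval 45.3 to 48.2), 38.3% of list 2 (37.4 to 39.1) and 58.2% of list 3 (57.1 to 59.3), a mean of 47.7% ± 9.99 (SD, n = 3). Each pair of lists overlapped more than 1000 shuffles of the second list over the genome did. Of list 1, 43.0% overlapped list 2 (15.1% in shuffles) and 34.3% overlapped list 3 (9.04%), and of list 2, 33.4% overlapped list 3 (7.60%). The one-sided empirical p was 0.001 for every pair and direction, the smallest that the shuffles can give. Simulated lists of the same lengths with no shared sites still gave 1805 regions in at least 2 lists and 93 in all 3, the number that list length alone gives. Without replicate 2 the count of consensus regions was 1553 and without replicate 3 it was 1944.

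Sharing rose with peak strength. Between the weakest and the strongest of 4 equal bins by p, the shared share went from 30.3% to 76.4% in list 1, from 14.7% to 78.1% in list 2 and from 33.0% to 93.4% in list 3. Of the 100 strongest peaks, 99%, 97% and 97% of lists 1, 2 and 3 lay in regions of all 3 lists. Across regions, the fold enrichments of lists 1 and 2 had a Spearman rho of 0.697 over 1942 regions, those of lists 1 and 3 a rho of 0.661 over 1557, and those of lists 2 and 3 a rho of 0.531 over 4126. Regions are not independent replicates and no p is given for these 3 values. The false discovery rate (FDR) column, made by swapping PIF1 and wild type, stood at 100% for all 4578 peaks of list 1, for 82.5% of list 3 and for no peak of list 2. In list 2 it still reached 66.61%. An FDR of 5% or less was given to 0, 1350 and 5 peaks of lists 1, 2 and 3.

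**Figure D1:**
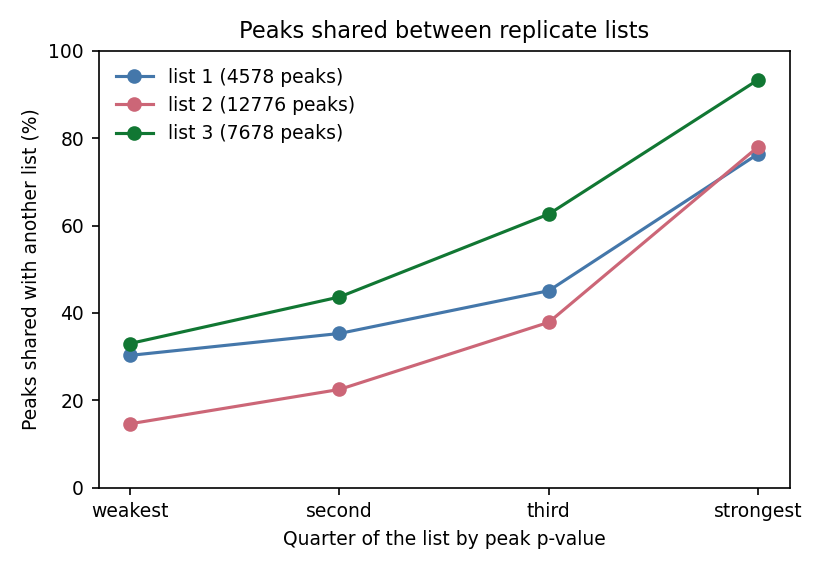
Share of the peaks of each list that lay in a region of at least 1 other list (percent, vertical axis), in 4 equal bins of the list by peak p-value from weakest to strongest (horizontal axis). Each line is 1 of the 3 lists, and the strongest bins reach 76.4%, 78.1% and 93.4% in lists 1, 2 and 3.

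The second comparison placed the regions relative to genes. Regions lay outside genes and close to them more often than shuffled positions did, as at PIL1, BBX28 and YUC8, an auxin synthesis gene with a region 489 bp away. Of the 4845 consensus regions, 42.9% (95% Wilson interval 41.5 to 44.3) lay up to 1000 bp outside a protein-coding gene, against 20.4% of shuffled positions, and 12.1% (11.2 to 13.1) lay 1000 to 2000 bp outside, against 7.47%. Inside a gene lay 35.8% (34.4 to 37.1), against 54.1%, and 9.23% (8.44 to 10.1) lay more than 2000 bp from any, against 18.0%. The one-sided empirical p, adjusted over the 4 classes, was 0.001 for each. The shuffles covered whole chromosomes and were not matched on gene density. Of consensus regions, 2.66% lay in the gene-poor 1 Mb bins described below, which made up 12.4% of bins. The shuffled 18.0% may thus partly reflect gene-poor parts. Consensus regions moved by 20000 bp lay inside a gene at 61.1%, so the share inside was also lower than at nearby positions. In the single lists the share inside a gene was 54.3%, 42.1% and 43.0% (46.5% ± 6.79, SD, n = 3), and the share up to 1000 bp outside was 20.9%, 37.9% and 34.9%. List 1 as a whole thus lay close to these whole-chromosome shuffled values in both classes. It was not compared with positions matched on gene density. By support, the share inside a gene was 52.6% for regions of 1 list, 38.5% for those of 2 and 28.9% for those of all 3.

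**Figure D2:**
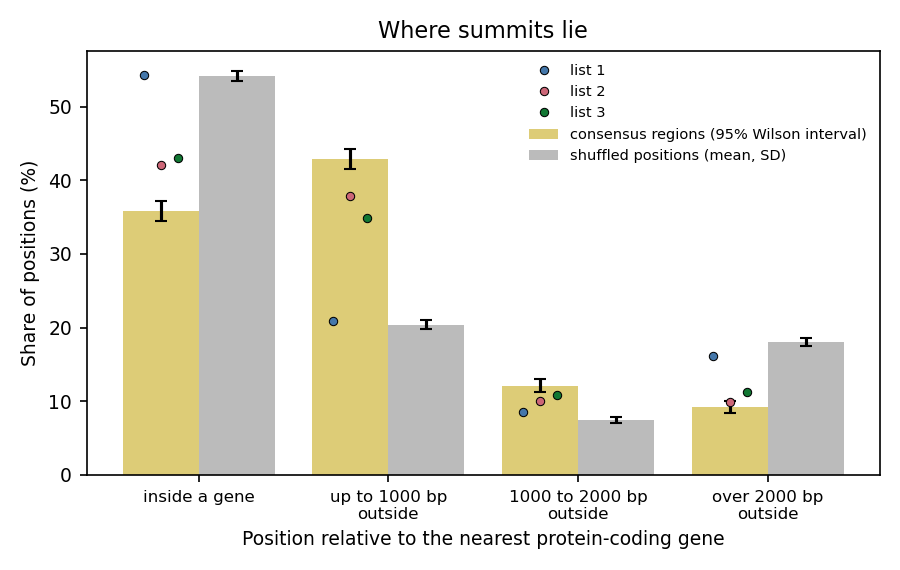
Share of summit positions (percent, vertical axis) by place relative to the nearest protein-coding gene (horizontal axis). Yellow bars are the 4845 consensus regions with 95% Wilson intervals, grey bars the mean and SD of 1000 shuffles, and points the single lists. 42.9% of consensus regions lie up to 1000 bp outside a gene, against 20.4% of shuffled positions.

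The third comparison asked which genes lay next to the regions. The listed genes of auxin, brassinosteroid, abscisic acid and ethylene pathways had consensus regions more often than other genes. So did those listed for the circadian clock, light signalling, class II homeodomain-leucine zipper proteins and cell wall expansion. In all, 6536 of 27444 protein-coding nuclear genes (23.8%) had a consensus region inside or within 2000 bp of either end, and 2023 (7.37%) had one held by all 3 lists. Of the 4845 consensus regions, 1949 had 2 such genes in this window, 519 had 3 and 63 had 4 or more. Each gene was counted, so a region may lie nearer to another gene than to the named one. At PIL1 (1208 bp away), ASY3 was nearer (426 bp). Regions of IBH1, ATHB4 and XTH15 lay 1986, 1840 and 1746 bp away. Of 16 gene lists, 8 were over-represented and 0 were under-represented at an adjusted p under 0.05 (Fisher's exact test, two-sided, Benjamini-Hochberg over the 16 lists).

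The auxin list had 31 of 36 members next to a consensus region (odds ratio 19.9, 95% interval 7.68 to 65.6, exact adjusted p = 7.46e-14). SAUR22 and SAUR23 were counted through the same region. Fisher's test treats members as independent, so the interval may be too narrow. YUC8 had fold enrichments of 10.71, 46.05 and 14.12 in lists 1, 2 and 3, and YUC9 of 5.53, 21.01 and 7.27. Regions inside IAA14 and 602 bp from IAA7, genes of auxin-response repressors, had 7.15, 13.2 and 8.62, and 5.6, 12.84 and 9.41. The list holds selected members of its families. Genes were also grouped into 95 families by symbol after the data were seen. Of genes with IAA, SAUR and ARF symbols, 12 of 24, 9 of 16 and 11 of 23 had a consensus region. None of these 3 groups passed the threshold (Fisher's exact test, exact adjusted p = 0.0978, 0.0978 and 0.115 over the 95 families). These are not counts of whole families, since members under other symbols are missed. IAA3 (SHY2), IAA4 (ATAUX2-11) and IAA17 (AXR3) had regions and were not among the 24. The brassinosteroid list had 23 of 28 members (odds ratio 14.8, 5.49 to 49.7, exact adjusted p = 9.78e-10), among them IBH1 (12.07, 34.21 and 14.64), BEE3 (7.51, 25.46 and 12.78) and CIB1 (7.65, 17.02 and 15.89), which encode helix-loop-helix proteins. BAS1, for a brassinosteroid-inactivating enzyme, had 17.56 and 10.69 in lists 2 and 3.

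The clock list had 18 of 26 members (odds ratio 7.21, 2.98 to 19.2, exact adjusted p = 4.88e-06), with PRR9 (8.37, 25.47 and 15.8), LNK2 (7.92, 30.02 and 10.19), CDF5 (7.09, 14.57 and 18.32) and GI (5.76, 15.39 and 7.1). The light-signalling list had 27 of 42 (odds ratio 5.78, 2.96 to 11.7, exact adjusted p = 1.55e-07), led by PIL1, BBX29, BBX28 and PIF6 (PIL2 in the gene table). Of 20 genes with BBX symbols, grouped after the data were seen, 8 had a consensus region (Fisher's exact test, exact adjusted p = 0.461 over 95 families). BBX20 (BZS1) and BBX24 (STO) had regions but stand under other symbols. Some listed BBX genes without a region were missed in the same way. The abscisic acid list had 14 of 19 (odds ratio 8.97, 3.05 to 31.8, exact adjusted p = 1.99e-05). SOM, a zinc-finger gene that represses seed germination, had 7.27, 37.04 and 9.71, ABF3 had 5.54, 19.65 and 7.93, and CYP707A2, for an abscisic acid catabolic enzyme, had 4.92, 15.39 and 7.23. DAG1 had 8.43 and 5.38 in lists 2 and 3. With peaks of at least 10-fold alone, 0 of the 19 abscisic acid genes remained next to a region. That filter left a small share of all genes next to a region, so this does not set the list apart from other genes.

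All 5 class II homeodomain-leucine zipper genes on the list, which holds selected members, had a consensus region (lower bound of the odds ratio 2.93, exact adjusted p = 0.00175). ATHB4 (HB4) had fold enrichments of 8.6, 31.46 and 24.52, HAT1 of 5.93, 27.55 and 12.59, HAT2 of 4.15, 11.42 and 13.33, and ATHB2 of 6.52 and 3.7 in lists 2 and 3. With a window of 1000 bp the odds ratio of this list was 1.18 (exact adjusted p = 1). In all, the list lost its call in 2 of 16 alternatives and was reversed in 1. The ethylene list had 11 of 17 members (odds ratio 5.87, 1.99 to 19.3, exact adjusted p = 0.00106), with ACS8 (6.33, 19.7 and 13.07), ACS5 (5.77, 33.69 and 9.08) and EIL1 (4.01, 17.65 and 8.3). Its exact adjusted p was 0.363 with peaks of at least 10-fold alone and 0.0700 with a window of 5000 bp. The cell wall list had 11 of 21 (odds ratio 3.52, 1.36 to 9.26, exact adjusted p = 0.0086), with XTH15 (7.51, 37.73 and 25.55), EXPB1 (4.15, 14.26 and 5.72), CESA3 (CEV1 in the gene table, 10.4 and 7.33 in lists 2 and 3) and EXPA8 (12.72 and 5.23 in lists 2 and 3). For regions of all 3 lists the cell wall list had an exact adjusted p of 0.103. Its members too are selected. Of genes grouped by symbol after the data were seen, 10 of 30 XTH genes and 6 of 23 EXPA genes had a consensus region. Neither group passed the threshold (Fisher's exact test, exact adjusted p = 0.593 over 95 families for XTH).

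**Figure D3:**
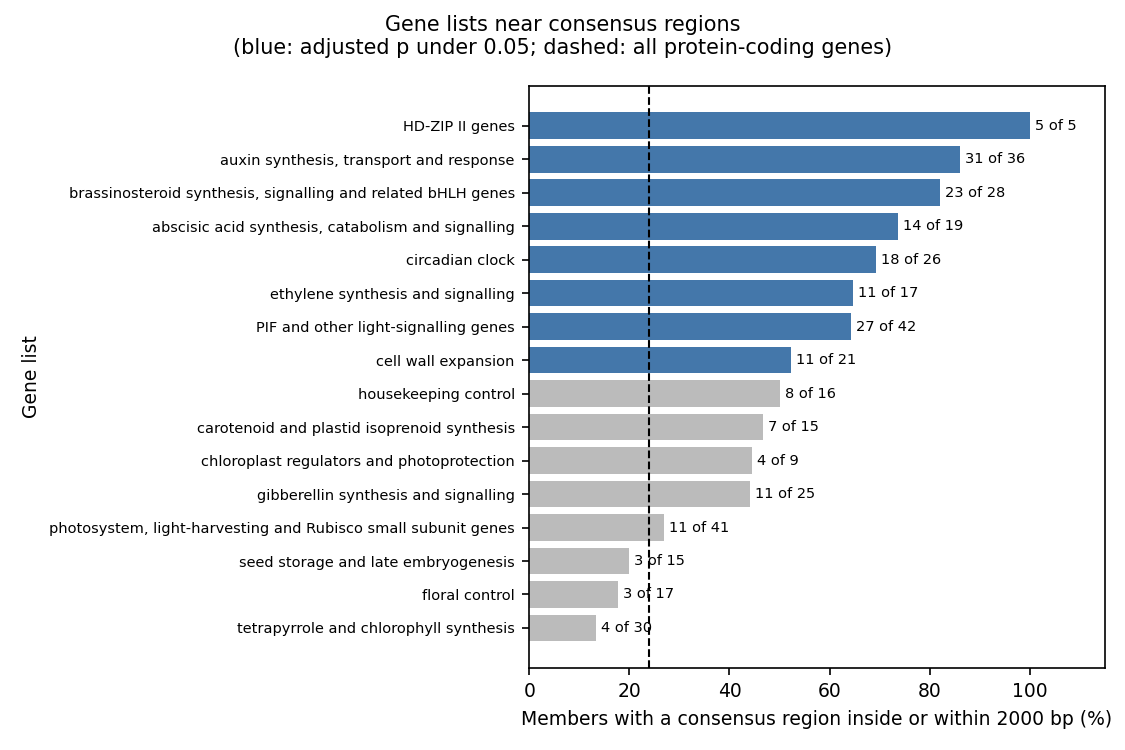
Percent of the members of each gene list with a consensus region inside or within 2000 bp (horizontal axis), for the 16 lists (vertical axis), with counts beside the bars. Blue bars have an adjusted p under 0.05, the dashed line is the 23.8% of all protein-coding genes, and the auxin bar reaches 31 of 36.

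For the other 8 lists the test did not pass the threshold. The gibberellin list had 11 of 25 members (odds ratio 2.52, 1.03 to 5.97, exact adjusted p = 0.0532), among them RGA (RGA1), a repressor of gibberellin responses (6.08, 20.72 and 10.49), GA2OX6 (5.8, 12.66 and 13.85), GID1B (4.71, 16.51 and 10.4) and GA20OX3 (4.5, 15.55 and 7.25). For regions of all 3 lists its exact adjusted p was 0.0167. The carotenoid list had 7 of 15 (odds ratio 2.80, 0.864 to 8.84, exact adjusted p = 0.0893, and 0.00952 for regions of all 3 lists), with BCH2 (5.01, 12.18 and 12.89), ZEP (ABA1, 5.62, 13.96 and 6.03), BCH1 (3.1, 7.93 and 6.95) and PSY, for phytoene synthase (2.94, 6.34 and 7.33). The housekeeping control list had 8 of 16 (odds ratio 3.20, 1.05 to 9.79, exact adjusted p = 0.0532), with TUB6 (3.97, 14.36 and 5.66), ACT2 (3.77, 10.78 and 5.56) and PP2AA3 (6.01 and 4.12 in lists 2 and 3). Under 4 of 16 alternatives this control list passed the threshold. Its share of 50% was close to the 52.4% of the cell wall list, so the call of that list does not set it apart from this control.

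Chloroplast regulators had 4 of 9 members (odds ratio 2.56, exact adjusted p = 0.284), with GNC (5.92, 9.86 and 7.57), GUN1 (3.86, 7.59 and 3.25), SIG5 (SIGE, 11.88 and 8.52 in lists 2 and 3) and SIG2 (3.14 and 3.16 in lists 2 and 3). Photosystem, light-harvesting and Rubisco small subunit genes had 11 of 41 (odds ratio 1.17, exact adjusted p = 0.815), with PSBQ2 (10.47, 34.53 and 7.86), LHCB2.3 (5.4, 17.5 and 6.79), RBCS1A (3.76, 13.57 and 10.71) and PSBS (NPQ4, 7.34, 6.31 and 8.24). Chlorophyll synthesis had 4 of 30 (odds ratio 0.492, 0.125 to 1.42, exact adjusted p = 0.273), namely HEMF1 (LIN2, 14.84 and 7.26 in lists 2 and 3), PPOX1 (3.97, 12.02 and 6.86), PORB (5.53 and 5.86 in lists 2 and 3) and PORA (6.06 and 3.57 in lists 2 and 3). The seed storage list had 3 of 15 (odds ratio 0.80, exact adjusted p = 1), namely CRA1, CRB (CRU2) and CRU3, and the floral control list 3 of 17 (odds ratio 0.685, exact adjusted p = 0.829), namely AP3, SHP2 and PI.

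**Figure D4:**
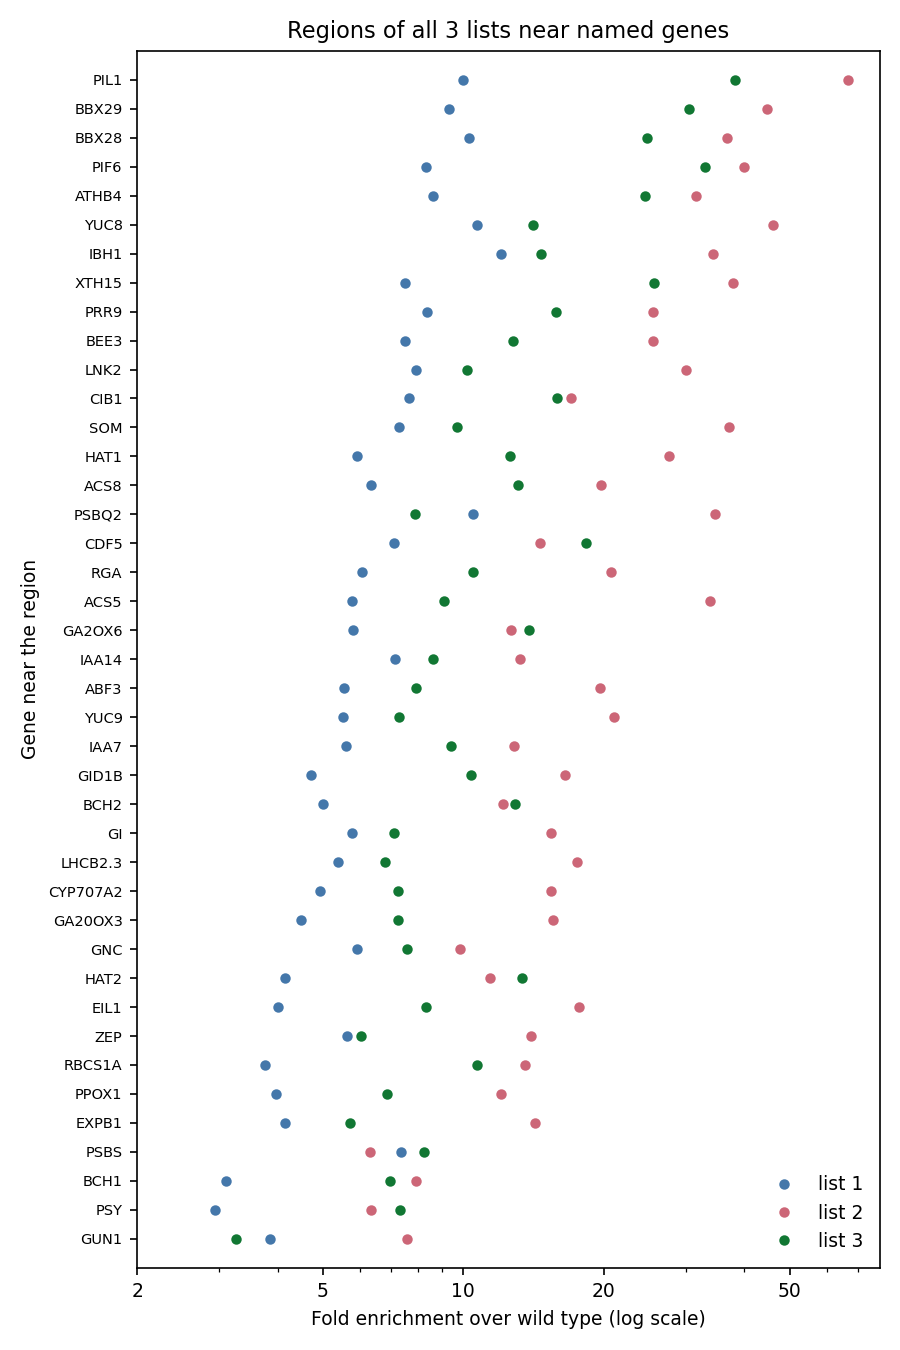
Fold enrichment over wild type on a log scale (horizontal axis) of regions held by all 3 lists, beside the named list genes (vertical axis), 1 point per list. PIL1, at the top, has fold enrichments of 9.99, 66.73 and 38.28 in lists 1, 2 and 3.

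The fourth comparison concerned PIF1 itself and its relatives. Peaks lay inside the PIF1 gene (PIL5 in the gene table) in all 3 lists. Consensus regions also lay 143 bp from PIF3 (11.98 and 4.14 in lists 2 and 3), inside PIF5 (PIL6, 4.82 and 2.94 in lists 2 and 3), 608 bp from PIF6 (8.33, 39.83 and 32.95 in lists 1, 2 and 3) and beside PIL1, while PIF4 and PIF7 had none inside or within 2000 bp. At PIF1, list 1 held peaks at chromosome 2, 8704237 to 8705269 and 8705352 to 8706599 (fold enrichments 3.16 and 4.03), list 2 held 8704405 to 8705101 (5.42), and list 3 held 8704483 to 8705115 and 8705345 to 8706444 (2.89 and 3.38). These peaks covered 76.4%, 23.3% and 58.0% of the gene, and none reached beyond it. The tagged line carries added copies of PIF1 sequence, so these peaks are not counted as evidence of binding, and PIF1 is 1 of the 27 light-signalling genes above.

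Peaks were also counted along the chromosomes. None lay on an organelle chromosome. Consensus regions numbered 44.0, 38.8, 39.6, 38.2 and 40.9 per Mb on chromosomes 1 to 5. In the 15 of 121 bins of 1 Mb with fewer than 100 protein-coding genes lay 2.66% of consensus regions. Of peaks in a single list, 15.5%, 4.39% and 9.03% of lists 1, 2 and 3 lay there, against 3.36%, 2.19% and 2.15% of shared peaks.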

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

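Of the tests in this part, that of library depth was chosen only after the result was seen. The FDR column of the peak lists was not used to select peaks, and it implies as many peaks of wild type over PIF1 as of PIF1 over wild type in 2 of the 3 lists. At the p cutoff it implies at least 4578 such peaks for list 1, 8506 for list 2 and at least 7678 for list 3, where the values for lists 1 and 3 are lower limits because the column stops at 100%. The 100 strongest peaks of list 1 argue against a list without enriched places in common with the others, since 99% of them overlapped both other lists, against at most 7% in shuffles that kept the distance to genes. That overlap does not show that these places were bound by PIF1. Deeper wild-type than PIF1 libraries may add to the swapped peaks and cannot be told apart from other sources with 1 pair of libraries per list. The list with the highest FDR, list 1, had a wild-type to PIF1 tag ratio of 1.22, below the 1.3 of list 3 but above 1. By the rule set for this test, depth fails where the list with the highest ratio lacks the highest FDR among its 300 strongest peaks. At the 300th peak the FDR was 27.33% in list 3 and 100% in list 1, so the prediction failed. The reading was changed to undecided after these values were seen, because 3 lists give no spread and wild type was deeper in each. A biological difference between the overexpressing line and wild type was not tested.

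The peaks at PIF1 itself lay inside the gene in each list. A summit inside the gene was found in 3 of 3 lists, as extra copies of the gene from the tagged transgene would give. Binding of the tagged protein next to its own gene would have given peaks within 2000 bp outside it, and 0 of 3 lists had one. Binding inside the gene stays open, since it may give the same peaks as the transgene.

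For the over-represented gene lists, 8 of 8 passed the threshold again against random lists matched on flanking intergenic length, which argues against long flanking space as the whole cause. A preference for active genes in general cannot be told apart from a preference for these pathways. Members were selected from general knowledge, so the lists do not stand for whole pathways. Whether that selection raised their shares was not tested. The housekeeping list had an odds ratio of 3.20, with an interval (1.05 to 9.79) that includes the median of 8.09 of the over-represented lists, and its 16 members are too few to decide. No test of expression was run.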

How the results depend on the processing

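The alternatives that leave out gene-poor bins, leave out the densest 1% of peaks, match lists on gene length, count only regions outside genes, leave a replicate out of the overlap ratio, or apply the fold, FDR and list-length filters and overlap rules to the list tests were chosen after seeing the data. Counts of regions depended on the threshold. From 4845 consensus regions and 6536 genes, a score of at least 100 left 2391 and 3475, a fold of at least 10 left 265 and 366, equal list lengths left 2880 and 4154, and support by all 3 lists left 1390 and 2023. An FDR of at most 1%, met by 0, 179 and 2 peaks of lists 1, 2 and 3, left 1 region and 1 gene. Leaving out 1 replicate gave 1553 to 4130 regions, 2226 to 5661 genes and 8 to 10 over-represented lists, with the lowest counts without replicate 2 (1553 and 2226) and without replicate 3 (1944 and 2762). A window of 5000 bp gave 11046 genes, the nearest gene alone 4091, and regions outside genes alone 4015. Other counts of regions and genes stayed within 1.5 times.

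The number of over-represented lists was 8, and 6 to 10 under every alternative except an FDR of at most 1%, where it was 1. With the 1 gene left there, the share of members next to a region was 0% for the light-signalling, class II homeodomain-leucine zipper, abscisic acid, auxin, brassinosteroid, ethylene and clock lists, which follows from having 1 gene. The share for the abscisic acid list was also 0% at a fold of at least 10 (exact adjusted p = 1, against 6.83e-06 to 1 over its alternatives), where 366 genes were left. The cell wall list lost its call in 6 of 16 alternatives, the ethylene list in 2 and the class II homeodomain-leucine zipper list in 2, apart from the reversals. The gibberellin list passed in 9, the housekeeping list in 4, the carotenoid list in 2 and the photosystem list in 1, and the cause was not tested. Overlap between lists was 3.70 times the shuffled value (2.83 to 9.52 over its alternatives), and the share inside genes was 35.8% (31.5% to 39.9%), with the same direction under each alternative run. No paired analysis was possible because only peak lists, in which each PIF1 library was already compared with 1 wild-type library, were analysed here. Alternatives for motifs were not run, and those with windows around transcription starts were run with windows around both gene ends. The weakest peaks by p were shared least in each list.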

Other observations

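All gene families and positions in this paragraph and the next were chosen after the data were seen, as was the comparison of single-list peaks with the share of gene-poor bins, whereas the other tests of single-list peaks were not. Grouping genes by the letters that open their symbol gave 95 families of at least 15 members, and 2 had consensus regions more often than other genes (Fisher's exact test, two-sided, Benjamini-Hochberg over the 95). Of genes with HB symbols, a group that includes homeobox genes, 25 of 37 had one (odds ratio 6.69, exact adjusted p = 2.02e-06). Among them were HB17, HB31 and HB33, and 2 of the 37 belong to the lists used above. Whether all 37 are homeobox genes was not checked. Of WRKY transcription factor genes, 34 of 67 had one (odds ratio 3.31, exact adjusted p = 8.80e-05), among them WRKY33, WRKY40 and WRKY6, and 0 belong to those lists. Both families also passed a permutation test against 10000 random lists matched on flanking intergenic length, with 9.51 and 17.9 members on average (adjusted p = 0.0095 for each). A family by symbol can mix unrelated genes and can miss members that stand under other symbols.

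Of the 6536 genes, 865 had 2 consensus regions, 79 had 3 and 6 had 4, the last being AT1G21000, RBOH F, PUB9, AT3G57540, AT4G22990 and OBP4. GAI, ARF6 and PIN3 were among those with 3. Of the 447 regions more than 2000 bp from any protein-coding gene, 21.7% had a long non-coding RNA gene within 2000 bp, against 7.29% of random positions that were also more than 2000 bp from them. Against random positions in the same 1 Mb bin the share was 15.4%, with an odds ratio of 1.52 (Fisher's exact test, adjusted p = 0.00129 over 4 gene types). Pseudogenes went the other way, with 17.7% of these regions within 2000 bp of one, against 65.3% of random positions and 35.2% of those in the same bins (odds ratio 0.395, Fisher's exact test, adjusted p = 5.14e-15). For tRNA and miRNA genes the test in the same bins did not pass the threshold (Fisher's exact test, adjusted p = 0.801 and 0.447). For long non-coding RNA genes and pseudogenes the difference was smaller within the same bins than over the whole genome. The peak with the most tags per kb in each list had a low fold enrichment. List 1 held 11034 tags at chromosome 2, 3394701 to 3402566, at a fold of 1.36, and lists 2 and 3 held a peak with the same bounds, chromosome 3, 14201378 to 14201823, at 2.17 and 1.62.

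Peaks found in a single list were set against 2 hypotheses. If they lie near the p cutoff, sharing should rise with strength. It rose by at least 46.1 percentage points from the weakest to the strongest of 4 equal bins in each list. Other accounts of single-list peaks may give such a rise too, so it does not set this hypothesis apart. For multi-copy sequence in gene-poor parts of the chromosomes, the share of single-list peaks there was at least 2.01 times that of shared peaks in each list. Peaks placed at random would also pass that ratio, since 12.4% of the 1 Mb bins are gene-poor and shared peaks lay there less often. Single-list peaks lay there at 15.5% in list 1 and below the share of bins in lists 2 and 3 (4.39% and 9.03%), so the ratio does not bear out a contribution of multi-copy sequence, which stays open.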
